A study of Arabidopsis thaliana with 27 samples.

How the data were processed

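Poly(A) RNA from Arabidopsis thaliana seeds was sequenced by the authors in 3 genotypes, the wild type Col-0 (WT) and the mutants hid1 and phyB, at 12, 24 and 48 h of darkness after red light. Per the labels, plants of all genotypes grew together, seeds were dried for about 2 months, received white light for 1 h and then a red pulse lasting 5 min, at a fluence rate of 20 μmol m-2 s-1, which activates phytochrome B. Libraries came from 1 μg of total RNA with a TruSeq RNA kit and were read as 150 bp pairs on a HiSeq instrument. The labels name no strand protocol and no mutant alleles. The submitters' processing notes list fastp, HISAT2 2.1.0 and SAMtools 1.6 with the TAIR10 genome. The counting tool, its strand setting, its treatment of reads that match several genes and the annotation version are not given in the sources used here.

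The deposited count table held raw counts, 1 column for each of the 27 libraries, as whole numbers without normalization. The deposited FPKM table held fragments scaled to transcript length and library size as 1 mean per group of 3 replicates. It gave no replicates, so no test rests on it alone: it served for the correlation between the mutant effects under another unit, for transcript lengths implied by counts and FPKM, and for gene symbols and locus types. Of 33612 rows in the count table, 5633 had no count in any library. Totals per library lay between 14750212 and 26293148 counts. No pair of libraries was a duplicate: over the 27 pairs of replicates within a group, the spread between libraries was 2.04 to 19.6 times that of counting alone, over genes with a summed count of at least 10. Fold changes against groups with 0 counts are given as bounds against a floor of 3 counts over the group, and ratios against 1 to 3 counts with 95% counting intervals. Both combine the 3 replicates of a group and cover counting error only, so the larger spread between libraries given above is left out. The reads carry no molecular identifiers, so even counting error is covered only if each read stands for 1 molecule.

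Libraries were grouped by genotype and time as labelled, which gave 9 groups of 3 biological replicates. Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by two-sided quasi-likelihood F tests after filterByExpr and TMM scaling, in 1 fit of all libraries with 1 coefficient per group and 18 residual degrees of freedom. The filter left 20465 genes. P values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 are said to have passed the test. Normalised levels are CPM (counts scaled to a library of 1e+06 counts) on TMM-scaled library sizes of the tested genes. The 13 comparisons were hid1 with WT, phyB with WT and hid1 with phyB at each time, the WT changes from 12 to 24 h and from 24 to 48 h, and the change of each mutant effect between 12 h and 48 h as an interaction. The comparisons, their tests, the gene lists and the rule for named genes were chosen before the data were examined.

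The rule names the 6 largest rises and 6 largest falls in each comparison of a mutant with WT and of WT over time, among genes that passed the test, with at least 10 CPM in the higher group and no overlap between replicates. From each list that was called, it adds up to 4 members with the smallest p. HID1, PHYB, the genes of ABA synthesis and breakdown, GA3OX1, GA3OX2, DOG1, SOM, ABI3, ABI5 and PIF1 (PIL5 in the table) belong to the named genes in every comparison, though not every value of theirs is printed. A gene without a symbol is printed only where it is among the 2 largest of its direction, apart from genes said in the text to have been chosen later.

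The 20 gene lists covered ABA biosynthesis, ABA catabolism, ABA signalling and dormancy, gibberellin (GA) biosynthesis, GA catabolism, GA signalling, phytochrome signalling, seed storage and oil bodies, late embryogenesis abundant proteins, cell wall loosening, lipid reserve mobilisation, cell cycle and DNA replication, photosynthesis and chlorophyll, cytosolic ribosomal proteins, heat shock proteins, auxin response and transport, the circadian clock, endosperm markers, embryo meristem and epidermis markers, and seed coat flavonoid markers. Of their 297 genes, 271 were tested. Of the 6 endosperm markers tested, 5 also stand in other lists (EXPA2, MAN7, NCED6, NCED9 and CYP707A2), so that list does not count as separate evidence. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 260 tests of lists and comparisons, and again with a correlation estimated from the data, whose adjusted p is given beside it. Counts of changed members are over all genes tested, and a count adjusted over the list alone follows where it differs. A further list, of the unfolded protein response, was fixed after the genes at 12 h had been seen but before its own values were.

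The effects of hid1 and phyB share their 3 WT libraries. Their correlation and covariance across genes are therefore printed beside values simulated 20 times with mutants equal to WT, and beside the count of shared genes that independent changes would give (n1 × n2/N). With 3 WT libraries per time these could not be divided into parts of 2 or more for separate use, so part of the excess may come from shared controls.

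The steps were tested on simulated data before use. In a resampled comparison of hid1 with WT at 12 h, over 20348 genes, 62 of 67 genes changed by 1.5-fold, 66 of 67 changed by 2-fold and 66 of 66 changed by 4-fold were recovered, with 14 false calls. A planted list was called and 0 of the random lists were. A planted covariance of 0.251 was returned as 0.25.

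Counts of changed genes and the genes named by the rule were recomputed with edgeR RLE size factors, without the filter, with replicate number as a block, with DESeq2 1.42.0, from the groups compared alone, and without each replicate in turn. The called lists were recomputed under the same alternatives except DESeq2 and the groups alone. Scaling by total counts, leaving out organelle and ribosomal RNA genes, and leaving out the 50 most abundant genes were chosen after seeing the data.

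The table has its own HID1 entry, which was used. Before the data were examined, HID1 had been equated with AT2G32795, which held 4.31 CPM in hid1 and 4.57 CPM in WT at 12 h and so was not the deleted transcript. AT2G35750 and the small nucleolar RNA AT2G35744 were lost with HID1, with 0 to 2 counts per group in hid1, and were not counted as separate observations. In WT at 12, 24 and 48 h HID1 held 1334, 987 and 849 counts, AT2G35750 1226, 812 and 694, and AT2G35744 256, 428 and 260. Whether these entries overlap HID1 or were lost beside it was not tested. Chromosomes and neighbours came from the TAIR10.1 annotation, in which all 297 list genes were found. Since the labels name TAIR10 and not that version, no coordinates are printed.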

Results

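Transcripts of Arabidopsis thaliana seeds were counted at 12, 24 and 48 h of darkness after a red light pulse that activates the photoreceptor phytochrome B. Wild-type Col-0 (WT) seeds were set beside seeds of hid1, a mutant of the noncoding RNA HID1, and of phyB, a mutant of the photoreceptor itself. Each of the 9 groups of genotype and time held 3 biological replicates, 27 libraries in all. Totals per library lay between 14750212 and 26293148 counts. Of 33612 genes in the table, 20465 held enough counts to be tested. The series asks whether HID1 favours germination under phytochrome B by holding down the synthesis of abscisic acid (ABA), the hormone that keeps seeds dormant. Germination itself was not analysed here, only transcripts.

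HID1 transcripts were almost absent from hid1 seeds. WT seeds held 24.5 ± 2.53 CPM at 12 h, 15.9 ± 1.31 CPM at 24 h and 10.9 ± 2.14 CPM at 48 h (SD, n = 3). The 3 hid1 libraries held 2 counts together at 12 h, 0 counts at 24 h and 1 count at 48 h. The ratio of WT to hid1 was 679 at 12 h (95% counting interval 188 to 5610) and 691 at 48 h (124 to 27300). At 24 h HID1 was at least 312-fold lower in hid1. In phyB seeds HID1 fell by 0.37 ± 0.12 (SE) on the log2 scale at 12 h and by 0.55 ± 0.13 at 24 h, and was higher than in WT at 48 h, by 0.96 ± 0.12. With scaling by total counts HID1 in phyB stood at -0.23 at 12 h and 0.28 at 48 h, and these 2 calls ended (adjusted p = 0.136 and 0.0596), while at 24 h it stood at -0.78. The phyB libraries labelled 12 h and 24 h held 18.9 ± 1.41 and 10.9 ± 0.588 CPM of HID1. An exchange of these labels stays open, as described below, and would put HID1 in phyB above WT at 24 h. PHYB transcripts remained in phyB seeds, at 56.7 ± 2.28 CPM against 116.6 ± 2.63 CPM in WT at 12 h and 69.7 ± 4.42 CPM against 124.9 ± 0.982 CPM at 24 h (log2 -1.04 ± 0.06 and -0.84 ± 0.06). At 48 h PHYB was 0.23 ± 0.06 above WT in phyB with TMM scaling (adjusted p = 0.000754) and below WT, at -0.45, with scaling by total counts. In hid1 seeds PHYB did not pass the test at 12 h and 24 h (log2 0.00 and -0.09) and was 0.64 ± 0.06 above WT at 48 h.

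**Figure D1:**
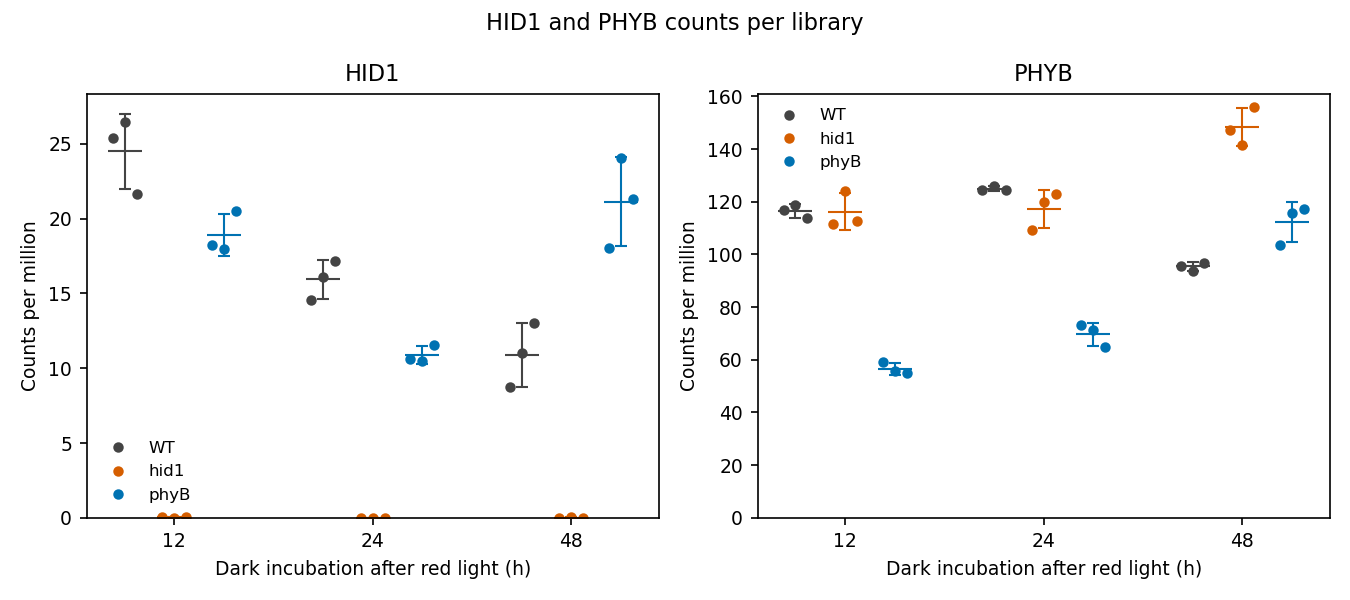
Normalised counts (CPM) of HID1 and PHYB at 12, 24 and 48 h of darkness in WT, hid1 and phyB; points are libraries, bars the mean and SD of 3 replicates. HID1 lies near 0 in all hid1 libraries, while PHYB in phyB is lower than in WT at 12 h and 24 h; at 48 h the PHYB difference changes sign with scaling by total counts.

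The WT time course describes how transcripts differed between times after phytochrome B was activated. Between 12 h and 24 h, transcripts for reserves and drying tolerance fell and those for cell wall loosening rose. Of the genes for seed storage proteins and oil bodies, 15 of 15 fell (median log2 -2.71, camera adjusted p = 2.19e-08, adjusted p = 0.174 with an estimated correlation), among them the oleosin OLEO4 (AT3G27660) at -3.21 ± 0.17 (SE, n = 3 per group). Of 18 late embryogenesis abundant genes, which protect drying tissue, 17 fell and 1 rose (median -1.70, adjusted p = 2.21e-09, adjusted p = 0.202 with an estimated correlation). Heat shock genes fell in 14 of 17 cases (median -2.08, adjusted p = 0.000254, adjusted p = 0.368 with an estimated correlation), among them the seed heat shock factor HSFA9 (AT5G54070), from 45.1 ± 2.55 to 1.86 ± 0.666 CPM. Cell wall loosening genes rose in 17 of 18 cases (median 2.04, adjusted p = 1.65e-10, adjusted p = 0.0466 with an estimated correlation). The xyloglucan-modifying enzyme XTH31 rose by 6.90 ± 0.26 and the expansin EXPA9 (AT5G02260) by 3.58 ± 0.11. Cell cycle genes rose in 20 and fell in 3 of 34 cases (median 1.02, or 1.19 with genes of 0 to 3 counts at their bound, adjusted p = 0.000104, adjusted p = 0.163 with an estimated correlation).

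ABA signalling and dormancy genes fell in 15 and rose in 3 of 19 cases from 12 h to 24 h in WT (median -0.76, camera adjusted p = 0.000605, adjusted p = 0.106 with an estimated correlation). The phosphatase gene AHG1, a restraint on ABA responses, changed by -2.04 ± 0.07 and the transcription factor ABI5 (AT2G36270) by -1.02 ± 0.07. Since the list holds restraints such as AHG1 beside other genes, its direction is not that of ABA signalling in any comparison. The call of ABI3 in this list, at -0.17, did not hold: it stood at 0.12 with scaling by total counts (adjusted p = 0.174) and also lost its call with RLE scaling, without the filter, without WT replicate 2 at 12 h and without each WT replicate at 24 h. The dormancy gene DOG1 (AT5G45830) fell by 2.98 ± 0.48, from 1.69 ± 0.448 to 0.214 ± 0.205 CPM (-4.07 without WT replicate 3 at 24 h). The list of ABA biosynthesis was not called (2 rose and 5 fell of 10, adjusted p = 0.218), and the rise of ABA2 lost its call without WT replicate 2 or 3 at 12 h (adjusted p = 0.0553 and 0.0517) and the fall of ABA3 with scaling by total counts (adjusted p = 0.778). ABA1 (AT5G67030), which encodes zeaxanthin epoxidase, fell by 1.85 ± 0.08. NCED9, which encodes the carotenoid-cleaving step, fell by 1.51 ± 0.11. GA3OX2, which makes active gibberellin, rose by 2.71 ± 0.28, within a GA biosynthesis list in which 7 of 10 genes rose (median 0.81, adjusted p = 0.0453, adjusted p = 0.16 with an estimated correlation). PIL5 (AT2G20180, also called PIF1), which represses germination in darkness, fell by 1.06 ± 0.06, among phytochrome signalling genes of which 10 of 17 fell and 3 rose (median -0.38, adjusted p = 0.0472, adjusted p = 0.246 with an estimated correlation). Auxin genes rose in 6 and fell in 1 of 10 cases (median 1.02, or 1.38 with genes of 0 to 3 counts at their bound, adjusted p = 0.0184, adjusted p = 0.13 with an estimated correlation). Embryo marker genes rose in 6 and fell in 1 of 9 (adjusted p = 0.0438, adjusted p = 0.202 with an estimated correlation). The calls for GA biosynthesis, phytochrome signalling and auxin ended with scaling by total counts (adjusted p = 0.0508, 0.066 and 0.0688). The GA biosynthesis call also ended without WT replicate 1 or 3 at 12 h (adjusted p = 0.0508 and 0.0537). The phytochrome call ended without WT replicate 1 or 2 at 24 h (adjusted p = 0.0503 and 0.0535). The embryo call ended without WT replicate 2 at 12 h (adjusted p = 0.0559).

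In total 13405 genes passed the test between 12 h and 24 h in WT, 6774 higher and 6631 lower, of which 3108 rose and 1776 fell at least 2-fold. Scaling by total counts put 71.9% of the changed genes higher, against 50.5%. The median of all genes moved from 0.00 to 0.26 on the log2 scale. Mitochondrial transcripts took 0.0764 to 0.16% of counts in the 6 WT and hid1 libraries at 12 h and 0.0151 to 0.028% in all 9 libraries at 24 h. In all 9 libraries at 48 h they took 0.0969 to 0.236%. Ribosomal RNA took 0.261 to 0.768%, 0.0521 to 0.114% and 0.421 to 0.83% in the same sets of libraries. A preparation that differed between times cannot be told apart from time itself in the WT changes.

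Between 24 h and 48 h, WT seeds gained transcripts for chlorophyll synthesis and cell division. PORA (AT5G54190), which encodes an enzyme of chlorophyll synthesis, rose from 0 counts to 532 ± 124 CPM, at least 11000-fold, and PORB from 1.01 ± 0.412 to 754 ± 121 CPM. Photosynthesis and chlorophyll genes rose in 24 of 24 cases (median 3.05, camera adjusted p = 6.96e-06, adjusted p = 0.187 with an estimated correlation). Cell cycle genes rose in 30 of 34, with 2 lower (adjusted p = 1.73e-07, adjusted p = 0.0891 with an estimated correlation). The extensin genes HRGP1 and EXT6, for cell wall glycoproteins, were at least 9770-fold and 8410-fold higher at 48 h, and AT3G28550 and AT1G23720 at least 28100-fold and 23800-fold. The cell wall loosening list went both ways and was not called (9 rose and 8 fell of 18, adjusted p = 0.749). Extensin and Rubisco small subunit genes resemble one another, and how shared reads were counted is not given in the sources used here. Auxin genes rose in 9 and fell in 1 of 10 cases (median 2.05, adjusted p = 0.00885, adjusted p = 0.126 with an estimated correlation), IAA19 by 6.11 ± 0.31.

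The same interval brought further falls in WT of genes tied to dormancy and drying. ABI3 (AT3G24650), a regulator of seed maturation, fell by 2.98 ± 0.08, ABI5 by 2.55 ± 0.07 and SOM (AT1G03790), a repressor of germination, by 3.04 ± 0.09. DOG1 fell by 2.28 ± 0.98 (adjusted p = 0.0339) to 0.0350 ± 0.0346 CPM, a call that ended without WT replicate 3 at 24 h (log2 -1.20, adjusted p = 0.363) or replicate 1 or 3 at 48 h (adjusted p = 0.0716 and 0.0909), and was -3.03 without replicate 2 at 48 h. ABA signalling and dormancy genes fell in 13 and rose in 3 of 19 cases (median -1.38, adjusted p = 0.0012, adjusted p = 0.13 with an estimated correlation). Falls were also seen in 18 of 18 late embryogenesis abundant genes (median -3.10, adjusted p = 3.35e-10, adjusted p = 0.178 with an estimated correlation). Of the ABA biosynthesis genes 9 of 10 fell and ABA2 rose, but the list was not called (adjusted p = 0.0537), and 4 of the 9 falls lost their call under alternatives. NCED3 lost it with RLE scaling (adjusted p = 0.0858), without the filter (0.0678), with DESeq2 (0.162), without each WT replicate at 24 h in turn (0.0513 to 0.107) and without WT replicate 2 or 3 at 48 h (0.173 and 0.08). AAO3 lost it with RLE scaling and DESeq2 (adjusted p = 0.0915 and 0.121), ABA3 with DESeq2 (0.0628), and NCED2 without WT replicate 2 at 24 h or replicate 1 at 48 h (0.0681 and 0.0948). The endosperm markers fell in 6 of 6 cases (median -2.75, adjusted p = 0.0012, adjusted p = 0.0466 with an estimated correlation), among them the mannanase MAN7 by 2.88 ± 0.11 and the ABA hydroxylase gene CYP707A2 by 5.18 ± 0.16. Ribosomal protein genes fell in 18 of 19 cases (median -0.53, adjusted p = 0.00081, adjusted p = 0.501 with an estimated correlation). Storage and oil body genes fell in 8 of 15 (median -0.81, adjusted p = 0.0347, adjusted p = 0.568 with an estimated correlation), a call that ended without WT replicate 1 at 48 h (adjusted p = 0.0577). In total 16834 genes passed the test, 9049 higher and 7785 lower, and with RLE scaling the median of all genes moved from 0.07 to 0.18. The chloroplast share of counts in WT was 0.219 ± 0.0226% at 24 h and 0.0903 ± 0.0511% at 48 h (SD, n = 3). Mitochondrial and ribosomal RNA shares were higher at 48 h, as given above, and a difference in preparation cannot be told apart from time.

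**Figure D2:**
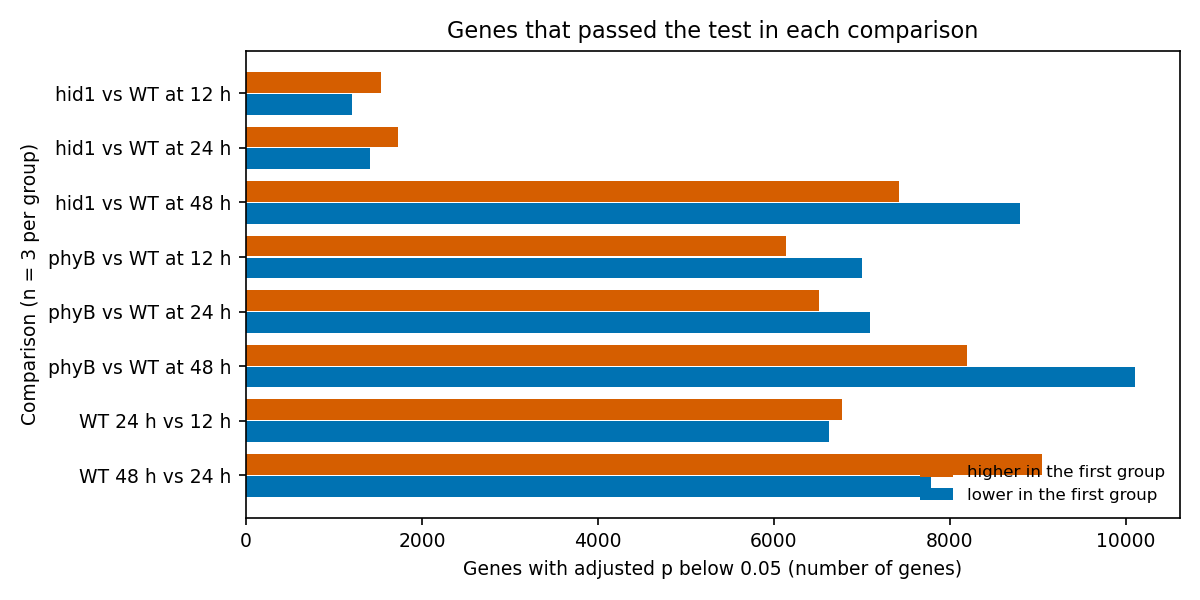
Number of genes with an adjusted p below 0.05 (edgeR, n = 3 per group) in each comparison, higher and lower in the first-named group. hid1 and WT differed in 2741 genes at 12 h, 3137 at 24 h and 16217 at 48 h, phyB and WT in 13144, 13598 and 18297.

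At 12 h the comparison of hid1 with WT asks what loss of HID1 changes early. Genes for cell wall loosening were higher in hid1, 11 of 18 over all genes and 12 adjusted over the list alone (median 0.82, camera adjusted p = 6.81e-16, adjusted p = 0.0359 with an estimated correlation). The expansin EXPA2 (AT5G05290) stood at 309 ± 35.5 CPM against 66.5 ± 4.72 in WT (log2 2.21 ± 0.16), EXPA9 was higher by 1.67 ± 0.10, and XTH19, a xyloglucan-modifying enzyme, by 1.82 ± 0.17. GASA6 (AT1G74670), a gibberellin-regulated peptide gene, was higher by 2.64 ± 0.25. Embryo marker genes were higher in 6 of 9 cases, 7 adjusted over the list alone (adjusted p = 7.07e-05, adjusted p = 0.0466 with an estimated correlation). Endosperm markers were higher in 2 of 6, EXPA2 and MAN7 (adjusted p = 0.000835, adjusted p = 0.0466 with an estimated correlation). Auxin transport genes AUX1 and PIN7 were higher by 0.98 ± 0.10 and 0.97 ± 0.10. The auxin list had 5 of 10 genes higher and was called as raised (adjusted p = 0.000254, adjusted p = 0.0466 with an estimated correlation), with a median of 0.35 (0.51 with genes of 0 to 3 counts at their bound) and a mean of the other sign, -0.07. Lipid mobilisation genes were higher in 7 of 15 cases, 9 adjusted over the list alone (adjusted p = 2.99e-05, adjusted p = 0.163 with an estimated correlation).

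ABA synthesis and breakdown differed in few genes between hid1 and WT at 12 h. Of 10 ABA biosynthesis genes 1 passed the test, ABA1, lower by a log2 value of -0.31 ± 0.07 (adjusted p = 0.00524), and the list was not called (adjusted p = 0.419). CYP707A1, which encodes an ABA hydroxylase, was the 1 of 5 breakdown genes that passed, at -1.42 ± 0.32 (list adjusted p = 0.174). ABI5 was lower (-0.36 ± 0.07) within an ABA signalling and dormancy list of 7 lower and 4 higher genes of 19, 12 and 4 adjusted over the list alone (adjusted p = 0.00133, adjusted p = 0.13 with an estimated correlation). DOG1 (AT5G45830) did not pass the test at 12 h (-0.82, adjusted p = 0.147), 24 h (0.61, 0.631) or 48 h (1.38, 0.261), at under 2 CPM, but passed at 12 h without hid1 replicate 2 (-1.61, adjusted p = 0.00655). Late embryogenesis abundant genes were lower in 5 and higher in 1 of 18 cases, 11 and 1 adjusted over the list alone (median -0.26, adjusted p = 0.000158, adjusted p = 0.4 with an estimated correlation). Photosynthesis genes were lower in 6 and higher in 1 of 24, 13 and 1 adjusted over the list alone (median -0.79, adjusted p = 0.00036, adjusted p = 0.272 with an estimated correlation). Heat shock genes were lower in 6 of 17, with 10 lower and 1 higher adjusted over the list alone (adjusted p = 0.00126, adjusted p = 0.42 with an estimated correlation), HSFA9 by -0.97 ± 0.13.

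GA signalling genes were higher in 4 and lower in 1 of 10 cases in hid1 at 12 h, 6 and 2 adjusted over the list alone, including RGL2, a DELLA repressor of germination, at 0.47 ± 0.07 (adjusted p = 0.0155, adjusted p = 0.163 with an estimated correlation). The higher genes were RGA1, GAI, RGL2 and RGL3, and the lower one was GID1A (-0.27). Since the list holds restraints such as RGL2 beside other genes, its direction is not that of GA signalling. Clock genes were lower in 4 of 10, 5 adjusted over the list alone (adjusted p = 0.00978, adjusted p = 0.178 with an estimated correlation), of which GI and PCL1 lost their call without WT replicate 2 (adjusted p = 0.0704 and 0.055), WT replicate 3 (0.0518 and 0.0977) or hid1 replicate 1 (0.0863 and 0.115). The cell cycle list, with 8 of 34 genes higher and 1 lower, was called as raised although its median was 0.02 and its mean -0.28 (adjusted p = 0.0447, adjusted p = 0.409 with an estimated correlation), and the median was 0.09 with genes of 0 to 3 counts at their bound. That call ended without WT replicate 2 or hid1 replicate 1 at 12 h (adjusted p = 0.0706 and 0.115). LSM1A (AT1G19120), part of the complex that starts mRNA decapping, was lower in hid1 at all 3 times (-4.29 ± 0.14 at 12 h), as was the transposable element gene AT5G43800.1, with a WT to hid1 ratio of 3290 at 12 h (95% counting interval 589 to 130000). The fitted log2 value of AT5G43800.1 was -11.24, and -13.15 without hid1 replicate 3. This gene also differed from WT by at least 4-fold in phyB at all 3 times. In total 2741 genes passed the test, 1532 higher and 1209 lower, of which 305 and 138 by at least 2-fold. Under scaling by total counts 47.4% of the changed genes were higher, against 55.9%. Without hid1 replicate 3 at 12 h the count was 1787.

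Storage protein genes separated hid1 from WT at 24 h. All 15 tested genes of seed storage and oil bodies were higher in hid1 (median 1.37, camera adjusted p = 3.33e-20, adjusted p = 0.0466 with an estimated correlation), the 2S albumin gene SESA4 (AT4G27170) at 314 ± 8.54 CPM against 19.3 ± 22.1 (log2 4.04, and 5.59 without WT replicate 3) and SESA1 at 191 ± 1.54 CPM against 25.1 ± 9.61. The 2S albumin genes are similar in sequence and may share reads, which was not tested, so these values may not be independent of one another. Late embryogenesis abundant genes were higher in 10 of 18 cases, 11 adjusted over the list alone (median 0.44, adjusted p = 9.08e-10, adjusted p = 0.202 with an estimated correlation). In WT both groups had fallen since 12 h.

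In ABA synthesis, NCED6 (AT3G24220) was higher in hid1 at 24 h by 2.11 ± 0.21 (adjusted p = 5.04e-08) and ABA1 by 0.51 ± 0.08 (adjusted p = 2.27e-05). NCED9 and AAO3, the aldehyde oxidase gene of the last step, were higher by 0.49 ± 0.12 and 0.32 ± 0.09, and ABA4 was lower (-0.39 ± 0.11). These 3 calls ended without WT replicate 1 at 24 h (adjusted p = 0.0527 for NCED9, 0.0741 for AAO3 and 0.0637 for ABA4). The AAO3 call also ended without hid1 replicate 3 (adjusted p = 0.13) and with scaling by total counts (adjusted p = 0.0672), and the ABA4 call without WT replicate 3 (adjusted p = 0.0624) or without hid1 replicate 1 or 2 (adjusted p = 0.0503 and 0.0518). The list of ABA biosynthesis, with 4 of 10 genes higher and 1 lower (4 and 2 adjusted over the list alone), was called as raised (median 0.28, adjusted p = 0.0418, adjusted p = 0.167 with an estimated correlation). The call ended without WT replicate 1 (adjusted p = 0.0593) and without hid1 replicate 3 (adjusted p = 0.0653) at 24 h, and with replicate number as a block. CYP707A2 was higher by 0.43 ± 0.09 within an uncalled list of ABA breakdown (2 of 5 higher, adjusted p = 0.373). The other call there, CYP707A1, ended with scaling by total counts (adjusted p = 0.0885), without each WT replicate in turn (0.0559 to 0.156) and without hid1 replicate 1 or 2 (0.0821 and 0.157). Endosperm markers were higher in 5 of 6 cases (adjusted p = 6.61e-05, adjusted p = 0.0359 with an estimated correlation), of which NCED6, NCED9 and CYP707A2 are the ABA genes just named.

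Gibberellin and ABA response genes differed as well at 24 h. GA3OX1 (AT1G15550) and GA3OX2, which make active gibberellin, were lower in hid1 by -1.41 ± 0.21 and -1.50 ± 0.23, and GA2OX2, which inactivates gibberellin, was higher by 1.45 ± 0.10, the 1 gene of 3 that passed in its list (adjusted p = 0.0133, adjusted p = 0.121 with an estimated correlation). Of 10 GA biosynthesis genes 4 were lower and 1 higher, 5 and 2 adjusted over the list alone (median -0.15, adjusted p = 0.0407, adjusted p = 0.147 with an estimated correlation), a call that ended without WT replicate 3 at 24 h (adjusted p = 0.0545). ABA signalling and dormancy genes were higher in 6 and lower in 2 of 19 cases, 8 and 2 adjusted over the list alone (adjusted p = 0.000598, adjusted p = 0.106 with an estimated correlation), AHG1 by 0.84 ± 0.07 and the stress gene LTI78 by 2.17 ± 0.20. ABI3, ABI5 and SOM did not pass the test (log2 0.06, 0.03 and 0.19). Heat shock genes were lower in 4 of 17 (adjusted p = 0.00517, adjusted p = 0.492 with an estimated correlation), and this call ended without WT replicate 3 (adjusted p = 0.21). QQS, an orphan gene tied to starch content, was higher by 5.11 ± 0.26 and the zinc finger gene PMZ lower (-2.64 ± 0.15). In total 3137 genes passed, 1731 higher and 1406 lower, and 1989 without WT replicate 1. Under scaling by total counts 37.9% of the changed genes were higher, against 55.2%.

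By 48 h hid1 seeds held far more transcripts of dormancy and drying genes than WT. ABI3 stood at 429 ± 6.04 CPM against 56.8 ± 4.56 (log2 2.92 ± 0.08), ABI5 at 247 ± 4.93 against 32.4 ± 4.36 (2.93 ± 0.07) and SOM at 496 ± 22.4 against 53.7 ± 7.04 (3.21 ± 0.09). ABA signalling and dormancy genes were higher in 13 and lower in 3 of 19 cases (median 1.38, camera adjusted p = 0.000254, adjusted p = 0.0891 with an estimated correlation). Late embryogenesis abundant genes were higher in 18 of 18 (median 3.60, adjusted p = 3.69e-13, adjusted p = 0.147 with an estimated correlation). Storage and oil body genes were higher in 15 of 15 (median 2.71, adjusted p = 3.89e-06, adjusted p = 0.243 with an estimated correlation). Endosperm markers were higher in 6 of 6 (median 2.29, adjusted p = 0.000403, adjusted p = 0.0466 with an estimated correlation).

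ABA biosynthesis genes were higher in 7 and lower in 1 of 10 cases in hid1 at 48 h (median 0.73, adjusted p = 0.0276, adjusted p = 0.163 with an estimated correlation). ABA1 was higher by 2.45 ± 0.08, at 113 ± 1.71 CPM against 20.8 ± 3.34, NCED6 by 4.09 ± 0.26, NCED9 by 2.42 ± 0.17 and NCED5 by 1.52 ± 0.32. AAO3 (0.84 ± 0.09), ABA4 (0.62 ± 0.11) and ABA3 (0.42 ± 0.09) were higher too, and ABA2, for the dehydrogenase step, was lower (-1.63 ± 0.13). Breakdown genes were also higher, 4 of 5, CYP707A2 by 4.45 ± 0.17 and CYP707A1 by 1.34 ± 0.10, although the list missed the threshold (adjusted p = 0.058), and the call of CYP707A3 ended with DESeq2 (adjusted p = 0.0548). The call of UGT71C5 ended with RLE scaling and DESeq2 (log2 0.15 in both, adjusted p = 0.12 and 0.151), without WT replicate 2 or 3 (adjusted p = 0.0733 and 0.0608) and without hid1 replicate 2 (adjusted p = 0.109). GA3OX1 was lower at -2.64 ± 0.19. PIL5 was higher by 0.44 ± 0.06.

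Genes of photosynthesis, auxin and the cell cycle were lower in hid1 than in WT at 48 h, while the cell wall loosening list went both ways and was not called (6 higher and 9 lower of 18, adjusted p = 0.697). Photosynthesis and chlorophyll genes were lower in 23 of 24 cases (median -2.85, adjusted p = 1.85e-05, adjusted p = 0.202 with an estimated correlation), PORB at 4.14 ± 1.70 against 754 ± 121 CPM. Auxin genes were lower in 9 of 10 (median -2.48, adjusted p = 0.000254, adjusted p = 0.0466 with an estimated correlation), IAA2 by -3.25 ± 0.13. Cell cycle genes were lower in 27 and higher in 1 of 34 (median -0.75, adjusted p = 0.00354, adjusted p = 0.249 with an estimated correlation). Ribosomal protein genes were higher in 17 of 19 by a small step (median 0.26, adjusted p = 0.0242, adjusted p = 0.635 with an estimated correlation), a call that ended without WT replicate 3 at 48 h (adjusted p = 0.0523). The methylesterase gene MES15 had 0 counts in hid1 and was at least 349-fold lower, and AT5G46890 had a WT to hid1 ratio of 3210 (95% counting interval 889 to 26500). Without hid1 replicate 2 the fitted log2 value of AT5G46890 was -13.87. Among the largest rises, AT5G59390 was higher by 7.29 ± 0.38 (7.88 without WT replicate 2) and QQS by 6.74 ± 0.27. In total 16217 genes passed, 7424 higher and 8793 lower, of which 2302 and 4762 by at least 2-fold.

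**Figure D3:**
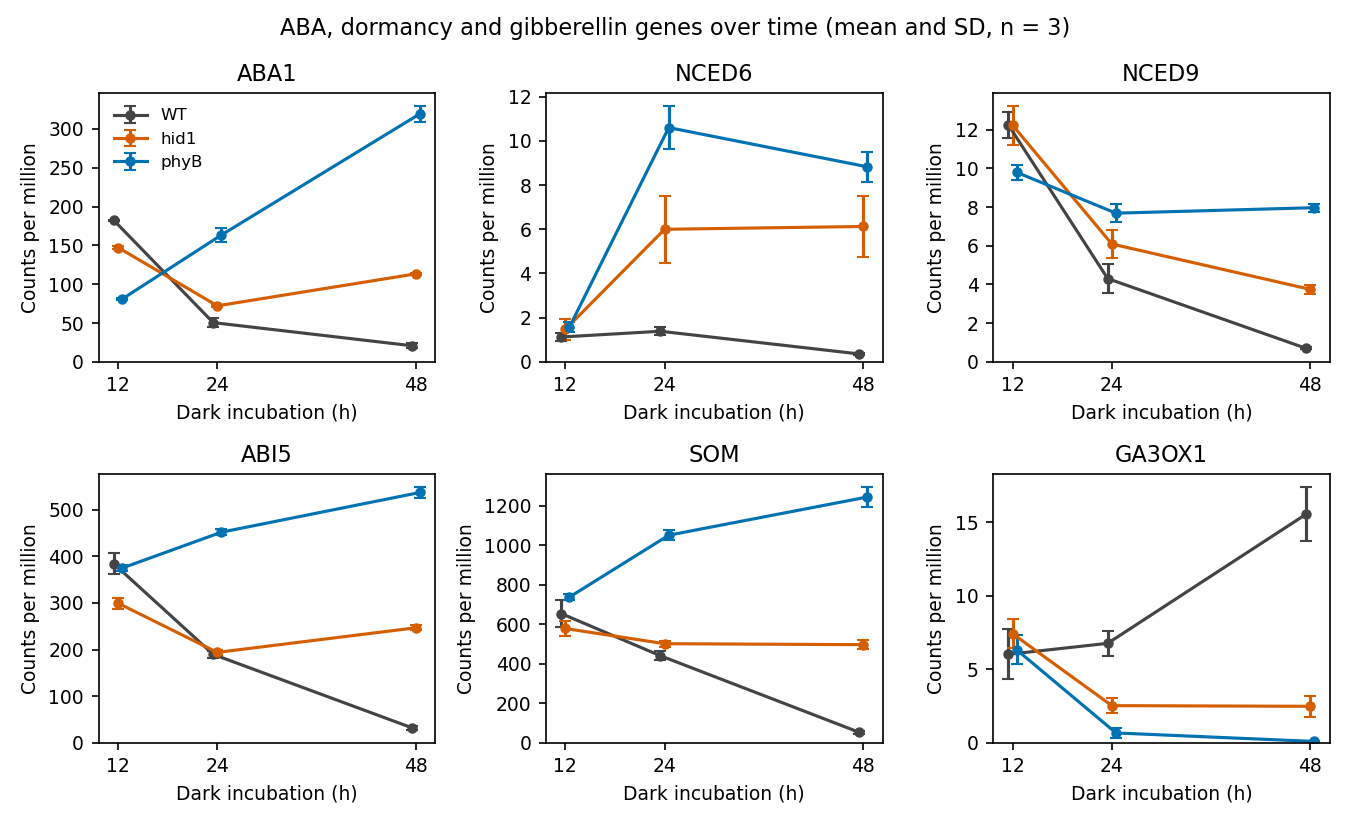
Normalised counts (CPM, linear axes from 0) of 6 genes of ABA synthesis, dormancy and gibberellin synthesis in WT, hid1 and phyB against hours of darkness, as mean and SD of 3 replicates. ABA1, NCED9, ABI5 and SOM fell in WT from 12 h to 48 h and at 48 h stood higher in hid1 and phyB, while GA3OX1 stood lower.

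For phyB the comparison with WT asks what the phyB mutation changes. In the libraries labelled 12 h, phyB seeds held fewer storage transcripts than WT, the reverse of later times. The cruciferin gene CRA1 (AT5G44120), for a main storage globulin, stood at 5585 ± 340 CPM against 27440 ± 3610 (log2 -2.30 ± 0.18). Storage and oil body genes were lower in 12 and higher in 1 of 15 cases (median -1.39, camera adjusted p = 0.00145, adjusted p = 0.4 with an estimated correlation). Late embryogenesis abundant genes were lower in 12 and higher in 2 of 18 (median -0.54, adjusted p = 0.0274, adjusted p = 0.616 with an estimated correlation). Photosynthesis genes were lower in 20 and higher in 1 of 24 (median -2.47, or -2.24 with genes of 0 to 3 counts at their bound, adjusted p = 0.00136, adjusted p = 0.324 with an estimated correlation), the Rubisco gene RBCS1A by -2.75 ± 0.16. Ribosomal protein genes were lower in 18 of 19 (median -0.64, adjusted p = 5.97e-05, adjusted p = 0.409 with an estimated correlation). The secretory GTPase gene SARA1A (AT1G09180) was higher by 9.26 ± 0.22, PMZ by 7.95 ± 0.18 and CHR34 by 7.34 ± 0.21.

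ABA biosynthesis as a list was not called in phyB at 12 h (2 higher and 4 lower of 10, adjusted p = 0.742), and of the 4 lower genes NCED9 lost its call with scaling by total counts (adjusted p = 0.148). ABA1 was lower (-1.17 ± 0.08), ABA2 and ABA3 were higher by 0.85 ± 0.15 and 0.66 ± 0.09, and the ABA hydroxylase gene CYP707A2 was lower (-0.97 ± 0.09). PIL5 was lower as well, at -1.35 ± 0.06, while ABI5 and SOM did not pass the test (log2 -0.03 and 0.17). SOM did pass as higher with RLE scaling (adjusted p = 0.0231), without the filter (0.0241), with replicate number as a block (0.0243) and with DESeq2 (0.0109). It also passed with scaling by total counts (log2 0.32, adjusted p = 0.000887), from the groups compared alone (0.0221) and without WT replicate 2 (0.00656). In total 13144 genes passed, 6139 higher and 7005 lower, of which 2155 and 2604 by at least 2-fold. Scaling by total counts put 56.7% of them higher, against 46.7%. The median of all genes then moved from -0.05 to 0.05. The 3 phyB libraries at 12 h stood apart in organelle and ribosomal RNA reads: mitochondrial transcripts took 0.0178 to 0.0202% of counts against 0.0764 to 0.16% in WT and hid1 at 12 h, chloroplast transcripts 0.086 to 0.0922% against 0.311 to 0.375%, and ribosomal RNA 0.0673 to 0.0796% against 0.261 to 0.768%. The 9 libraries at 24 h held mitochondrial and ribosomal RNA shares of 0.0151 to 0.028% and 0.0521 to 0.114%. CRA1 took 0.583% of counts in phyB at 12 h and 3.42% at 24 h, against 2.59% and 0.735% in WT.

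**Figure D4:**
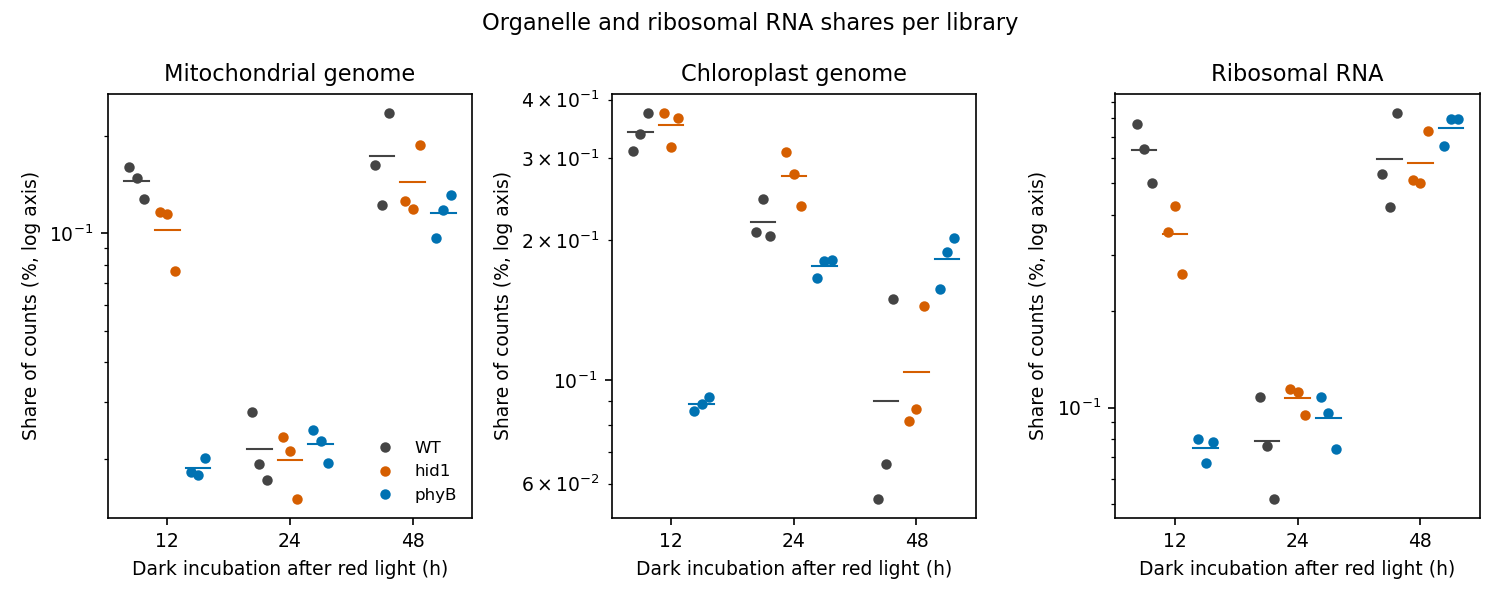
Share of counts (percent, log axes) from mitochondrial genes, chloroplast genes and ribosomal RNA in each library by genotype and hours of darkness; points are libraries and lines group means of 3 replicates. The 3 phyB libraries at 12 h lie below the 6 other libraries of that time in all 3 shares, and their mitochondrial and ribosomal RNA shares lie within the range of the 9 libraries at 24 h.

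In the phyB libraries labelled 24 h, reserve, drying and heat shock transcripts were high, and those of cell wall loosening, auxin and the cell cycle low. An exchange of labels between phyB at 12 h and 24 h stays open, so all results of phyB at 24 h rest on these labels. Storage and oil body genes were higher in 15 of 15 cases (median 2.76, camera adjusted p = 2.31e-08, adjusted p = 0.178 with an estimated correlation). Higher too were 18 of 18 late embryogenesis abundant genes (median 1.89, adjusted p = 9.74e-12, adjusted p = 0.164 with an estimated correlation), the dehydrin RAB18 by 3.17 ± 0.17. Heat shock genes were higher in 15 of 17, 16 adjusted over the list alone (median 2.00, adjusted p = 0.000158, adjusted p = 0.348 with an estimated correlation), HSFA9 by 3.99 ± 0.19. Cell wall loosening genes were lower in 15 and higher in 1 of 18 (median -3.35, adjusted p = 2.33e-09, adjusted p = 0.0548 with an estimated correlation), XTH31 at 4.05 ± 0.639 against 331 ± 27.7 CPM and EXPA15 by -4.03 ± 0.10. Auxin genes were lower in 7 of 10 (median -2.30, or -2.04 with genes of 0 to 3 counts at their bound, adjusted p = 0.000246, adjusted p = 0.0466 with an estimated correlation). Cell cycle genes were lower in 19 and higher in 1 of 34 (median -1.15, or -1.49 at the bounds, adjusted p = 0.000151, adjusted p = 0.164 with an estimated correlation), the replication gene MCM2 by -2.25 ± 0.11. Ribosomal protein genes were lower in 18 of 19 (median -0.52, adjusted p = 0.000158, adjusted p = 0.445 with an estimated correlation). Lipid mobilisation genes were lower in 11 and higher in 1 of 15 (median -0.46, adjusted p = 0.00321, adjusted p = 0.285 with an estimated correlation). Embryo markers were lower in 8 of 9 (median -0.59, adjusted p = 0.00368, adjusted p = 0.109 with an estimated correlation).

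Hormone genes of phyB at 24 h included GA3OX1 and GA3OX2, lower by -3.32 ± 0.29 and -5.71 ± 0.43 (GA3OX2 -6.95 without phyB replicate 3), and DOG1 (AT5G45830), higher by 3.02 ± 0.49, a value that WT replicate 3 lowered, at 1.75 ± 0.335 against 0.214 ± 0.205 CPM. ABA1 was higher by 1.69 ± 0.08, NCED6 by 2.93 ± 0.20 and NCED5 by 1.49 ± 0.16, in an ABA biosynthesis list with 6 of 10 genes higher and 2 lower (median 0.82, adjusted p = 0.0418, adjusted p = 0.167 with an estimated correlation). That list call ended with replicate number as a block. ABA signalling and dormancy genes were higher in 13 and lower in 5 of 19, 14 and 5 adjusted over the list alone (median 1.17, adjusted p = 0.000835, adjusted p = 0.109 with an estimated correlation), with SOM higher by 1.25 ± 0.08, ABI5 by 1.25 ± 0.07 and ABI3 by 0.47 ± 0.07. Photosynthesis genes were lower in 13 and higher in 2 of 24 (median -1.36, adjusted p = 0.0367, adjusted p = 0.498 with an estimated correlation). Clock genes were higher in 7 of 10 (median 0.44, adjusted p = 0.0392, adjusted p = 0.255 with an estimated correlation). Both calls ended with scaling by total counts (adjusted p = 0.17 and 0.0646). GASA2 and ATS3, an embryo-specific gene, were higher by 6.29 ± 0.27 and 5.98 ± 0.28. In total 13598 genes passed, 6509 higher and 7089 lower, of which 1964 and 2967 by at least 2-fold. Of these, 32.4% were higher with scaling by total counts, against 47.9%. The median of all genes then moved from 0.00 to -0.23.

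At 48 h phyB seeds differed from WT in 18297 genes, 8190 higher and 10107 lower. CRA1 alone took 12.5 ± 0.551% of counts in phyB (SD, n = 3) against 0.595 ± 0.162% in WT, and the 10 most abundant genes 30.1 ± 1.07% against 5.75 ± 0.264%. Storage and oil body genes were higher in 15 of 15 cases (median 5.66, camera adjusted p = 1.43e-05, adjusted p = 0.269 with an estimated correlation). So were 18 of 18 late embryogenesis abundant genes (median 5.19, adjusted p = 1.12e-09, adjusted p = 0.183 with an estimated correlation). Heat shock genes were higher in 17 of 17 (median 4.67, adjusted p = 0.000158, adjusted p = 0.355 with an estimated correlation), HSFA9 by 6.99 ± 0.19. Cell wall loosening genes were lower in 18 of 18 (median -3.22, adjusted p = 1.54e-05, adjusted p = 0.163 with an estimated correlation), EXPA9 at 1.92 ± 0.336 against 414 ± 63.6 CPM. Cell cycle genes were lower in 33 and higher in 1 of 34 (median -4.85, or -4.60 with genes of 0 to 3 counts at their bound, adjusted p = 7.76e-08, adjusted p = 0.0891 with an estimated correlation). Auxin genes were lower in 10 of 10 (median -5.71, or -5.26 at the bounds, adjusted p = 0.000671, adjusted p = 0.0607 with an estimated correlation). Photosynthesis genes were lower in 22 and higher in 1 of 24 (median -5.20, adjusted p = 0.000756, adjusted p = 0.324 with an estimated correlation). Ribosomal protein genes were lower in 18 of 19 (median -0.99, adjusted p = 0.00398, adjusted p = 0.564 with an estimated correlation). Lipid mobilisation genes were lower in 14 and higher in 1 of 15 (median -0.98, adjusted p = 0.0029, adjusted p = 0.279 with an estimated correlation). The transcription factor gene BZIP61 and the proline-rich protein gene PRP1 had 0 counts in phyB and were at least 857-fold and 877-fold lower.

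Most genes of the lists of ABA synthesis and of ABA signalling and dormancy were higher in phyB than in WT at 48 h. The second list includes restraints on ABA responses. ABA1 was higher by 3.95 ± 0.08, at 319 ± 10.5 against 20.8 ± 3.34 CPM, NCED6 by 4.61 ± 0.25, NCED9 by 3.50 ± 0.16, NCED5 by 3.32 ± 0.27 and ABA3 by 1.56 ± 0.09, while ABA2 and ABA4 were lower (-1.34 ± 0.13 and -0.86 ± 0.14). ABA biosynthesis had 7 of 10 genes higher and 2 lower (median 1.96, adjusted p = 0.0387, adjusted p = 0.167 with an estimated correlation). Breakdown genes went both ways, with CYP707A2 higher by 3.57 ± 0.20 and CYP707A3 lower (-2.28 ± 0.20), and were not called (3 higher and 2 lower of 5, adjusted p = 0.389). ABA signalling and dormancy genes were higher in 15 and lower in 4 of 19 (adjusted p = 0.000598, adjusted p = 0.106 with an estimated correlation), with SOM higher by 4.53 ± 0.09, ABI5 by 4.05 ± 0.08 and ABI3 by 3.79 ± 0.08. DOG1 was 101-fold higher (95% counting interval 33.9 to 494) and GA3OX2 147-fold lower (40.6 to 1220), while GA3OX1 was lower at -7.27 ± 0.38. Without WT replicate 2 the log2 value of DOG1 was 7.17, and without phyB replicate 2 that of GA3OX2 was -10.06. Clock genes were higher in 7 and lower in 2 of 10 (median 1.17, adjusted p = 0.0387, adjusted p = 0.272 with an estimated correlation), TOC1 by 2.13 ± 0.06. Of the seed coat flavonoid markers only 2 of 9 held enough counts, both lower in phyB at 48 h, and that list was called in no comparison (adjusted p = 0.318 here). With scaling by total counts 29.1% of the changed genes were higher, against 44.8%, and the median of all genes moved from -0.25 to -0.92, so that a log2 value of -0.25 here lies at the middle of all genes. ABA1 then stood at 3.26, ABI5 at 3.37 and ABA4 at -1.54.

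**Figure D5:**
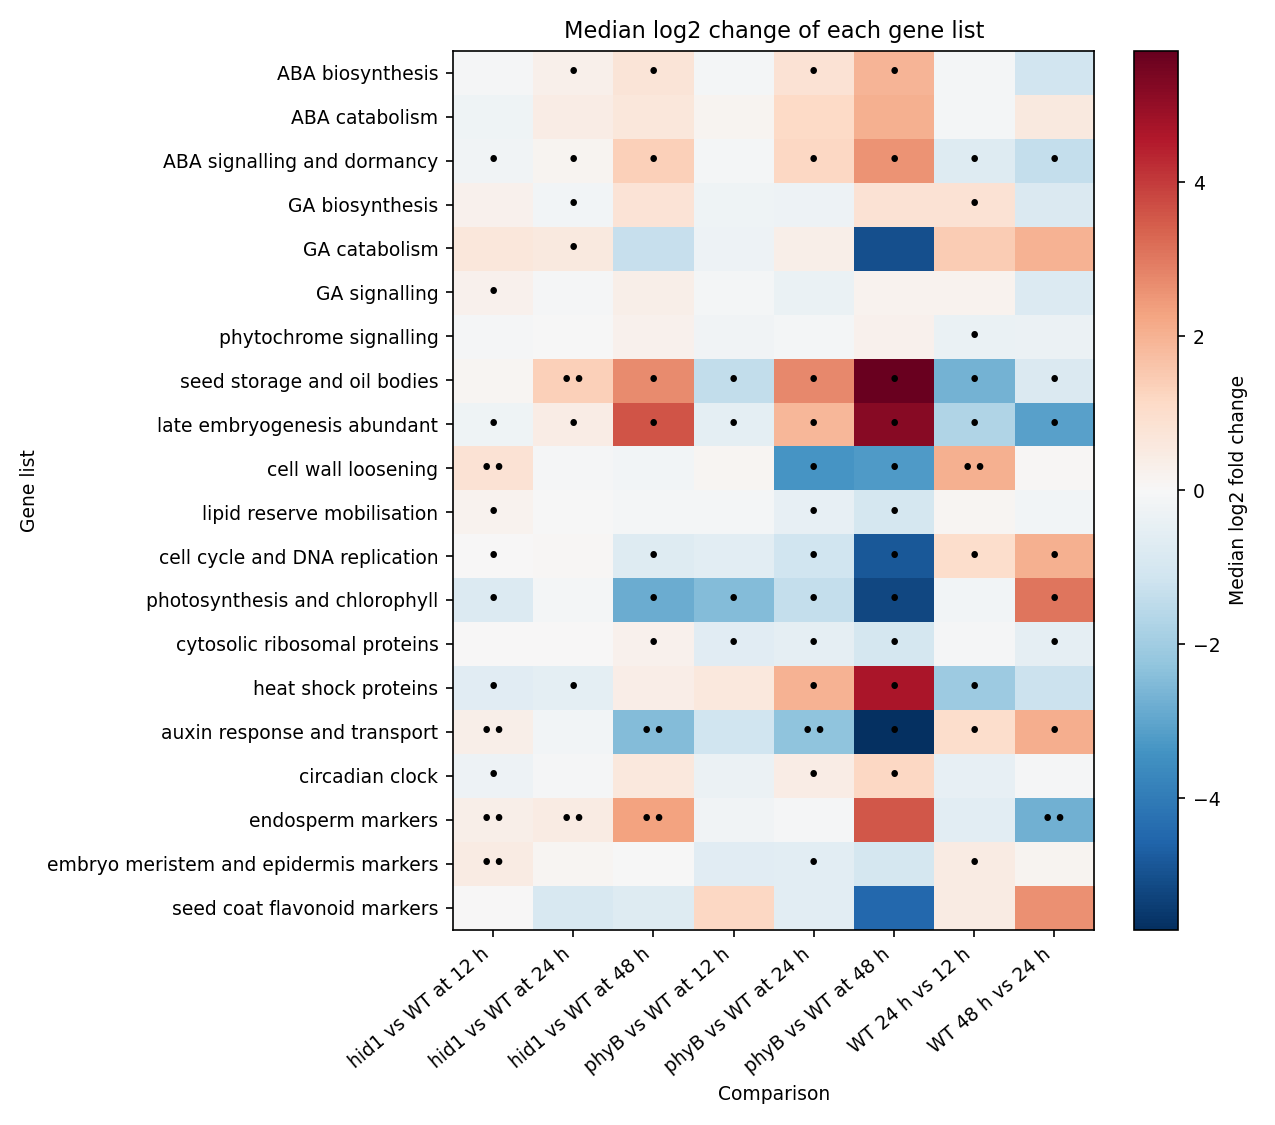
Median log2 fold change (colour scale) of the tested genes of each list in each comparison, the first-named group against the second, n = 3 per group. A dot marks a camera adjusted p below 0.05 with a preset correlation, 76 of 160 tests, and a double dot marks the 11 that also passed with an estimated correlation.

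Direct comparison of hid1 with phyB asks where the mutants part. At 12 h hid1 held more storage and ribosomal protein transcripts, with storage genes higher in 14 of 15 cases (median 1.99, camera adjusted p = 0.000209, adjusted p = 0.348 with an estimated correlation). Ribosomal protein genes were higher in 17 of 19, 18 adjusted over the list alone (median 0.68, adjusted p = 2.75e-05, adjusted p = 0.393 with an estimated correlation). Both rest on the 3 phyB libraries labelled 12 h, whose organelle and ribosomal RNA shares stood apart and in which CRA1 took 0.583% of counts, against 3.42% in those labelled 24 h. The results at 24 h rest in turn on the phyB libraries labelled 24 h. At 24 h cell wall loosening genes were higher in hid1 in 16 and lower in 1 of 18 cases (median 3.18, adjusted p = 1.4e-09, adjusted p = 0.0506 with an estimated correlation), EXPA15 by 4.72 ± 0.10, and heat shock genes lower in 15 of 17 (median -2.25, adjusted p = 8.7e-06, adjusted p = 0.278 with an estimated correlation). At 48 h cell cycle genes were higher in 34 of 34 cases (median 3.83, or 3.71 with genes of 0 to 3 counts at their bound, adjusted p = 1.35e-10, adjusted p = 0.0466 with an estimated correlation), MCM5 by 3.78 ± 0.09. Heat shock genes were lower in 17 of 17 (median -4.29, adjusted p = 1.12e-05, adjusted p = 0.285 with an estimated correlation). Storage genes were lower in 13 of 15 (median -2.84, adjusted p = 0.000432, adjusted p = 0.363 with an estimated correlation). ABA1 was higher in hid1 than in phyB at 12 h (0.86 ± 0.08) and lower at 24 h and 48 h (-1.18 ± 0.08 and -1.49 ± 0.07), and ABI5 was lower at 48 h (-1.12 ± 0.07). GA3OX1 was higher in hid1 at 24 h and 48 h, by 1.91 ± 0.34 and 4.63 ± 0.55. At 12, 24 and 48 h, 12970, 13474 and 16152 genes passed, 6928, 7020 and 8399 of them higher in hid1. With scaling by total counts the share higher was 41.4% against 53.4% at 12 h, 64.3% against 52.1% at 24 h and 77.0% against 52.0% at 48 h, with the median of all genes at 0.17 at 24 h and 0.73 at 48 h. At 48 h ABA1 and ABI5 then stood at -0.82 and -0.45, GA3OX1 at 5.26 and MCM5 at 4.45.

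Both mutant effects changed with time. Between 12 h and 48 h the difference of hid1 from WT moved up for ABA1 by 2.76 ± 0.11 and for ABI5 by 3.29 ± 0.10, both lower in hid1 at 12 h (-0.31 and -0.36) and higher at 48 h (2.45 and 2.93). It also moved up for SOM, by 3.39 ± 0.12, which did not pass the test at 12 h (-0.18), and turned down for the auxin carriers PIN3 (-3.19 ± 0.11) and AUX1 (-3.16 ± 0.13), which were higher in hid1 at 12 h and lower at 48 h. Late embryogenesis abundant genes moved up in 18 of 18 cases (median 3.92, camera adjusted p = 2.13e-18, adjusted p = 0.0947 with an estimated correlation). ABA biosynthesis genes moved up in 7 and down in 1 of 10 (median 0.72, adjusted p = 0.0274, adjusted p = 0.163 with an estimated correlation). Auxin genes moved down in 9 of 10 (median -3.15, or -3.16 with genes of 0 to 3 counts at their bound, adjusted p = 6.61e-05, adjusted p = 0.0396 with an estimated correlation). The phyB effect moved up for storage genes in 15 of 15 cases (median 6.76, adjusted p = 9.06e-07, adjusted p = 0.202 with an estimated correlation), and down for cell wall loosening genes in 18 of 18 (adjusted p = 7.92e-07, adjusted p = 0.106 with an estimated correlation). Its start, with storage genes below WT, rests on the same phyB libraries labelled 12 h. The difference itself passed the test in 13057 genes for hid1, 6381 up and 6676 down, and in 16280 for phyB, 7883 up and 8397 down. For phyB 29.4% of these were up with scaling by total counts, against 48.4%, and the median of all genes moved from -0.25 to -1.07.

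The hid1 and phyB effects were compared across genes to ask how far both mutants moved the same genes. At 48 h 5891 genes were higher in both mutants and 7647 lower in both, against 2971 and 4343 for independent changes, and 1462 moved in opposite directions, against 7185. ABA1, NCED6, NCED9, ABI3, ABI5 and SOM were among those higher in both, and PORB and PIN3 among those lower. At 12 h 630 genes were higher in both, 804 lower in both and 705 opposite, against 460, 414 and 887, and at 24 h 875, 919 and 786, against 551, 487 and 1047. Pearson's r across 20465 genes was 0.31 at 12 h, 0.27 at 24 h and 0.79 at 48 h, and 0.49, 0.48 and 0.44 in simulations with mutants equal to WT, since both effects share the WT libraries. The covariance was 0.28, 0.22 and 5.27, against 0.0139, 0.0128 and 0.0122 in the simulations. Part of the excess may come from the shared controls, which were not divided, and genes are not independent replicates, so no p is given. At 12 h r was 0.18 from the deposited group means of FPKM. The overlaps and r at 12 h and 24 h also rest on the labels of the phyB libraries, whose exchange stays open.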

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

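The tests of progress between the WT states of 24 h and 48 h, of shared organelle and ribosomal RNA reads, of exchanged labels and of a common shift of all genes, and the choice to leave out entries lost together with HID1, were chosen after the results were seen. A difference between groups, tested as an interaction in edgeR, singled out 3 results: the effect of hid1 differed between 48 h and 12 h in 13057 genes, that of phyB in 16280 genes, and the auxin list moved down between the times in hid1 by a median of -3.15. Of 100 splits of the samples drawn for each interaction, only the real one (1) gave as many genes, with 12495 genes in hid1 and 12145 in the highest other split, and 15836 and 13273 in phyB. These splits mixed genotypes within each time, so they test for no mutant effect at either time. A random grouping of that kind is excluded at a share of 0.05. The highest other splits kept the 48 h libraries in their groups, so the splits cannot show that the effects changed between 12 h and 48 h. For each of the 11 comparisons of 3 libraries with 3, the real split (1) gave more genes than the 9 others, of which the highest gave 0, but 10 splits cannot give a share under 0.05. The real splits gave 1986, 3953 and 15474 genes for hid1 with WT at 12, 24 and 48 h, 12335, 13475 and 17677 for phyB with WT, 12581, 13248 and 15173 for hid1 with phyB, and 12565 and 16184 for WT over time.

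At 12 h phyB differed from WT in 13144 genes, and its 3 libraries held low shares of organelle and ribosomal RNA reads. The tables argue against a preparation shared with the 24 h libraries as the whole source of the nuclear changes: the hid1 change from 12 h to 24 h followed the phyB effect over 4357 genes with a slope of 0.269, where a shared preparation as the whole source would need about 1, although r = 0.435 and 67.7% of these genes with the same sign leave room for a shared part. For the organelle and ribosomal RNA reads such a preparation stays open, since 2 of 3 shares lay in the range of the 24 h libraries. An exchange of labels between phyB at 12 h and 24 h also stays open: the mitochondrial share cannot part them, being low in both (at most 0.0202% and 0.0246%), the CRA1 shares of 0.583% and then 3.42% against 2.59% and 0.735% in WT go with it, as does phyB at 24 h lying nearer to WT at 12 h (0.828) than phyB at 12 h did (1.02, root mean square log2 distance), while against it phyB at 24 h also lay nearer to WT at 24 h (1.06 and 1.14), and the chloroplast share of phyB at 12 h (0.086 to 0.0922%) lay outside that of the 24 h libraries (0.166 to 0.309%). An unfolded protein response may also contribute: 15 of 15 genes of that list were higher (median 1.86, camera p = 8.59e-16, and p = 0.0088 with an estimated correlation), the chaperone gene BIP3 by 5.92 ± 0.32 (SE). That list was fixed after the genes at 12 h had been seen, so its p is not independent support. It also rose in WT from 12 h to 24 h (13 of 15, median 1.19) and was mostly lower than WT in phyB at 24 h (10 of 15, median -0.45) and 48 h (11 of 15, median -1.17). The effect of the phyB mutation itself remains open and untested.

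At 48 h both mutants differed from WT in most genes, which transcript length does not account for (Spearman's rho across genes -0.0564 in hid1 and -0.00279 in phyB). A few abundant genes in phyB cannot account for all of it through 1 common shift: without the 50 most abundant genes, 24.8% of genes lay at least 2-fold above the median of all genes and 30.7% below it, beyond 2 SE, whereas the 18201 genes that passed there are close to all tested genes and decide nothing. Against the WT change from 24 h to 48 h, r across genes was -0.879 in hid1 and -0.794 in phyB, but a state as far from WT at 24 h with unrelated deviations would give -0.907 and -0.77, so this leaves slower progress open. In hid1 the margin required below that reference lay beyond the lowest possible r, so the test could not have spoken for slower progress there. Against the WT change from 12 h to 24 h, r was -0.366 in phyB, where slower progress may contribute, and -0.0433 in hid1, which argues only against a stay of hid1 near the WT state of 12 h, since hid1 at 48 h lay nearest to WT at 24 h (root mean square log2 distance 0.910), while of 3108 genes that rose at least 2-fold then in WT 2171 were lower and 409 higher in hid1 at 48 h, and of 1776 that fell 959 were higher and 408 lower, which goes with slower progress. At 12 h the tests, against the WT change from 24 h to 48 h, left slower progress open (r = -0.271 in hid1 and -0.224 in phyB). In hid1 at 12 h the cell wall loosening, auxin and embryo marker lists were raised, as in WT from 12 h to 24 h. The late embryogenesis abundant, heat shock, and ABA signalling and dormancy lists were lowered, as in WT then. Taken alone, these directions would go against slower progress in hid1 at 12 h. Both comparisons subtract the same WT libraries at 12 h, however, so a deviation in those libraries would move the lists alike in both. These lists therefore cannot decide on slower progress in hid1 at 12 h. Storage genes that passed the test in hid1 at 12 h, such as CRU2 (1.14), were higher in hid1 and go with slower progress. Whether the mutations act on progress or on single genes was not tested.

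Some genes differed from WT at least 4-fold at all 3 times, 39 entries in hid1 (33 higher and 6 lower, of which HID1, AT2G35744 and AT2G35750 were lost together) and 276 in phyB (227 lower, 49 higher). LSM1A was lower in hid1 by -4.29, -4.35 and -3.42 at 12, 24 and 48 h, and QQS was higher in it by 4.47, 5.10 and 6.74. QQS also differed from WT by at least 4-fold in phyB at all 3 times. A segment of chromosome 2 carried with each mutation could give such constant differences, although neither of these 2 genes lies on that chromosome. Of the hid1 genes without those 3 entries, 4 of 36 lay there (11.1% against 15.4% of tested genes, Fisher's exact p = 0.645), or 6 of 38 with AT2G35744 and AT2G35750 kept, and of the phyB genes 46 of 276 (16.7% against 15.5%, Fisher's exact p = 0.558). Neither share differed beyond its spread. Most genes of both sets lay on other chromosomes, so a segment of chromosome 2 cannot hold them, and why they differed was not tested. For the genes on chromosome 2, a share over the whole chromosome cannot exclude a short segment, which stays open beside an effect of the mutations.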

How the results depend on the processing

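Scaling by total counts, leaving out organelle and ribosomal RNA genes, leaving out the 50 most abundant genes and the correlation with log2(FPKM + 0.1) were chosen after seeing the data. Of 338 values of 23 results under the alternatives, 331 counted as kept, 6 moved and 1 reversed. Numbers of genes and lists counted as kept within 1.5 times the main count. HID1 and PHYB counted as kept by direction and call alone. HID1 in hid1 at 48 h stood at -8.94, and reached -10.69 without a replicate. A correlation counted as kept within its jackknife standard error. Since that error came from the leave-one-out values themselves, these could hardly count as moved. Without hid1 replicate 3 at 12 h, 1787 genes differed between hid1 and WT, and without WT replicate 1 at 24 h, 1989. With an estimated correlation 11 of 160 list tests were called, against 76. PHYB in phyB at 48 h was -0.45 with scaling by total counts, against 0.23. The correlation of the mutant effects at 12 h was 0.18 with log2(FPKM + 1) and 0.20 with log2(FPKM + 0.1), against 0.31, and at 48 h it was 0.76 without the filter, against 0.79. Among named genes ABI3 reversed, at 0.12 with scaling by total counts against -0.17 in WT from 12 h to 24 h. The cause was not tested, except that leaving out a library lowers the number of samples and an estimated correlation widens the spread of each list.

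Without each replicate in turn, hid1 with WT gave 1787 to 2492 genes at 12 h, 1989 to 2743 at 24 h and 15732 to 16102 at 48 h. For phyB with WT the ranges were 12362 to 12655, 12829 to 13010 and 18136 to 18293, and for hid1 with phyB 12211 to 12450, 12630 to 13069 and 15634 to 16019. WT over time gave 12647 to 12885 and 16444 to 16672, the interactions 12360 to 13122 for hid1 and 15896 to 16278 for phyB, and the list calls 71 to 78. HID1 in hid1 lay between -9.53 and -8.69, -11.31 and -11.19, and -10.69 and -8.44, and PHYB in phyB between -1.07 and -1.02, -0.88 and -0.79, and 0.20 and 0.29. The correlation ranged over 0.28 to 0.37, 0.22 to 0.31 and 0.78 to 0.79.

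Replicate numbers are not stated to mark a shared source, and same-numbered libraries correlated above 0.1 in 9 of 108 pairs (-0.12 to 0.29, median 0.01), so they were not taken as pairs. As a hint from the data, 19 of 27 libraries correlated best with their own number, where unrelated numbers would give about 1 in 3. Replicate 3 of both WT and hid1 at 48 h held the highest mitochondrial shares of their groups (0.236% and 0.188%). A source shared by same-numbered libraries therefore stays open. With replicate number as a block, hid1 with WT gave 3006, 3351 and 16340 genes at 12, 24 and 48 h, phyB with WT 13218, 13681 and 18326, hid1 with phyB 13060, 13584 and 16203, WT over time 13494 and 16936, the interactions 13167 and 16304, and the lists 74 calls. The block ended the calls of cell cycle in hid1 at 12 h (adjusted p = 0.095), ABA biosynthesis in hid1 and phyB at 24 h (adjusted p = 0.0576 and 0.0584) and phytochrome signalling in WT from 12 h to 24 h (adjusted p = 0.0609), and no other list call. DESeq2 gave 2719, 2907 and 15744 genes for hid1 with WT and 12856, 13181 and 18472 for phyB with WT. Of 76 list calls, 76 were kept with RLE scaling, 76 without the filter, 72 with the block and 71 with scaling by total counts. Of the 43 further list calls, for hid1 with phyB and the interactions, 43 were kept with RLE scaling, without the filter and with the block, 40 with scaling by total counts and 3 with an estimated correlation, and 13 gene results printed for these comparisons kept their call and direction under 199 of 199 alternatives. Without each replicate in turn, these further list calls were kept in 358 of 360 cases. Of 547 results for named genes, 4 lost their call with RLE scaling, 2 without the filter, 6 with DESeq2 and 7 with scaling by total counts, and 58 of 3282 without a replicate. Tests on the FPKM table were not run, since it holds 1 value per group.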

Other observations

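HIL1, which has an entry of its own in the count table, was higher in hid1 than in WT at 12, 24 and 48 h, by 0.59, 0.60 and 2.47 on the log2 scale, and was looked at after the HID1 values had been seen. At 48 h HIL1 held 88 counts in WT and 402 in hid1, and the pseudogene AT2G35743 on chromosome 2 held 75 and 330. By its number AT2G35743 stands next to AT2G35744, which was lost with HID1. Whether HIL1 and AT2G35743 share reads, or their rise is tied to the mutated locus, was not tested. PAD3, CYP71A18 and CYP82C2, which encode enzymes of defence compounds, were higher in hid1 at all 3 times, CYP71A18 by 4.64, 3.82 and 4.39. In phyB the gibberellin-regulated gene GASA4 was at least 4-fold lower at all 3 times, and at 48 h held 0.565 CPM against 473 CPM in WT. MRD1, QQS, AT4G18900 and AT5G43800.1 differed at least 4-fold from WT in both mutants at all 3 times. These genes were chosen after their values were seen.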
